A study of Danio rerio with 2 samples.

How the data were processed

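The series held 1 LPS library and 1 control library of zebrafish larvae, each from the pooled tail regions of 12 larvae dissociated with enzymes. The tissue label reads body. Libraries were made with a droplet-based 3' kit with a target of 16000 cells per lane, per the labels' protocols. The deposited values were UMI counts per gene and barcode, which the authors made with Cell Ranger 6.1.2 against the GRCz11 genome, per the submitters' processing notes; the annotation release is not given. Every barcode in the deposited matrices had at least 500 UMIs in both libraries, so barcodes below that depth, and with them a direct measure of free RNA, were not available. The matrices listed 27419 gene identifiers with symbols, of which 24988 were also in the reference table of names, and 532 symbols belonged to more than 1 identifier. The symbols hp, cela1.5 and cxcl11.6 are among those shared, and each value given for them is of 1 identifier only. Genes with near-identical copies, such as the mmp13a pair, elastase and parvalbumin genes, are uncertain where reads could be split between copies.

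Cells with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs were kept. This removed 755 barcodes of the LPS library and 2056 of the control library, and the kept cells had a median of 1515 and 1729 UMIs. Doublets were scored with scrublet as built into scanpy 1.11.5 at an expected rate of 0.1. It called 0 in both libraries, because the highest scores (0.525 and 0.552) lay under its automatic thresholds (0.544 and 0.686), so no doublets were removed and the caller did not work on these data. Counts were log-normalised and both libraries were clustered together on 3000 variable genes, 40 principal components and 15 neighbours with the Leiden method (leidenalg 0.10.2, resolution 2, seed 0). Mitochondrial, ribosomal and preset response genes were left out of the clustering genes. No integration across libraries was applied.

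Clusters were named from 34 preset marker lists. A cluster took the name of a class with at least 5 markers among its 50 leading genes and a lead of 2 over the next class. No other class could have more markers among the 10 leading genes, and the top gene could not mark another class only. A cluster over 90% from 1 library, by share of each library's cells, was left unnamed. Its cells entered no class, standardised level or list median. A cluster under 33% of the median depth with no marker among those 10 genes was also left unnamed. The lists were fixed before the data were examined, but this naming rule was set after the clusters had been seen. Named classes are written with "-like", since they rest on markers only. The rule left 7699 LPS and 11669 control cells unnamed, and the looser rule of at least 3 markers with no lead named a further 606 and 814. Classes with at least 50 cells in both libraries, 19 of the 20, were used; osteoblast-like cells, at 7 and 6, were not.

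UMIs were summed per class and library and given as CPM, that is, scaled to a common total. A composition-standardised level weighted each class by its mean share of UMIs over the 2 libraries, so that a change in the mix of classes does not move it. Intervals of levels are exact Poisson, of ratios exact conditional binomial, and of shares exact Clopper-Pearson, all at 95%. There were no replicates, so no test, p-value or standard error is given. A gene was counted as at least 2-fold higher or lower when it had at least 200 UMIs over both libraries and its interval excluded 1, a rule of size. List medians used members with at least 20 UMIs and were placed among 10000 random lists of equal size matched on level; their ranges come from 200 redraws of the counts. The gene rps27l of the p53 list was left out there with the ribosomal genes, against the plan; with it that median was slightly under the 0.0852 printed, and the alternatives include it. List members were counted as higher or lower from 1.5-fold, and class values were given from 30 UMIs. For shares of cells with a UMI, cells were thinned to 700 UMIs, leaving out 2118 LPS and 179 control cells.

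The lists, comparisons and rule for naming genes were fixed before the data were examined. The rule named 29 preset genes, the 12 highest and 12 lowest standardised genes by the interval bound nearest to 1, the 5 highest and 5 lowest in the macrophage-like, neutrophil-like and 6 largest other classes, of which the text gives some, and up to 4 members per list by the bound farthest from 1. Mitochondrial and ribosomal protein genes were left out of the parts that rank all genes. Alternatives fixed at the same time were a stricter filter (at least 1000 UMIs, at most 10% mitochondrial), every barcode as given, called doublets kept, resolution 1, response genes kept in clustering, shares without erythroid-like cells, no standardisation, clusters as strata, equal class weights, TMM factors (edgeR 4.0.16, R 4.3.3), thinned cells, other floors (500 UMIs for gene counts, 1 for list members), 0.5 UMIs added, and subtraction of a background profile scaled by haemoglobin UMIs. Added after the data had been seen were shares over named classes only, removal of the highest 10% of doublet scores, the looser naming rule, naming of clusters of 1 library outside the low-depth ones from at least 3 markers, all alternatives for shares of other classes, the 5 highest cells of each gene left out per class, and genes no higher than in the low-depth clusters left out.

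The standardised comparison of LPS against control was tested on simulated data, first after the real values had been computed. Of 13652 simulated genes, 50 of 50 were found at 4-fold and 50 of 50 at 3-fold in each direction, 0 of 13452 unchanged genes were counted, and the interval held the true ratio for 95.6% of them. A list made with a log2 ratio of 1.58 had a median of 1.60, and 53 of 54 clusters kept their name. These values hold for simulated data only and do not show that the real intervals are wide enough. In the real data 5 cells could hold most of a gene's UMIs in a class, which intervals of counting error do not take in. Nor do the kept names show that naming is stable, since mucous-goblet-like cells were not named with the stricter filter or at resolution 1. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.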

Results

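Zebrafish larvae of the AB strain, 6 days after fertilisation, were immersed in medium with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria, here from Pseudomonas aeruginosa, or in medium alone. The labels gave the LPS amount as 37.5 with no unit and the immersion as 9.5 h, against 10 h in the sample title. By the protocol, tail regions of 12 larvae per group were pooled, dissociated and loaded on 1 lane of a droplet-based single-cell RNA-seq chip per group, so each group had 1 library. The LPS library held 16329 barcodes with 60244396 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule), a median of 1571 UMIs per barcode. The control library held 21359 barcodes with 108903518 UMIs and a median of 1932. After removal of barcodes with more than 25% mitochondrial UMIs or fewer than 200 genes, 15574 and 19303 cells were kept. The series title frames the study as a screen of how an inflammatory response is arranged in space under a uniform stimulus, and the comparison asks in which cells and genes the LPS library differed from the control library. With 1 library per group no difference has a replicate check, so none was tested. Every interval is a 95% interval of counting error only, and any other difference between the pools or lanes is part of each ratio.

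Matrix metalloproteinase 9 (mmp9), an enzyme that cleaves extracellular matrix and is induced at wounds, was 5.53-fold (5.09 to 6.02) higher in the LPS library, at 71.7 against 12.96 CPM after standardisation to a common mix of cell classes (CPM, a gene's UMI counts scaled to a common total per library and class). The log2 ratio was 2.47, and 1.60 with every class weighted equally. The gene was higher in 11 of 11 classes with at least 30 UMIs, and in 4 of 4 in thinned cells. Clusters of low-depth cells, used to estimate free RNA, held 49.7 against 13.4 CPM of mmp9, so free RNA may add to these class counts. The cytokine il1b was 14.3-fold higher in basal-epidermis-like and 20.6-fold higher in superficial-epidermis-like cells, in the latter with a log2 ratio of 2.75 without the 5 highest cells. It was 2.47-fold lower in neutrophil-like cells, where the log2 ratio was 0.17 in cells thinned to a common depth. Macrophage-like and neutrophil-like cells, the phagocytes of the innate immune system, had share ratios of 0.944 and 1.24, the former running from 0.613 to 1.61 over other settings. The median of the preset list of inflammatory cytokines and chemokines was below 0, but 0.088 in thinned cells, and the glucocorticoid-responsive gene fkbp5 was 3.06-fold (2.87 to 3.28) higher. RNA of the rod photoreceptor gene rho was higher in the LPS library in 12 of 12 classes with at least 30 UMIs, with 1184 UMIs against 4 in all named classes.

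Cells were grouped into 54 clusters, and 20 classes were named from preset marker genes. Macrophage-like cells numbered 316 (2.03% of kept cells, exact binomial interval 1.81 to 2.26%) in the LPS library and 415 (2.15%, 1.95 to 2.36%) in the control library, a ratio of 0.944 (0.813 to 1.1). Neutrophil-like cells numbered 64 in each library, 0.411% and 0.332%, a ratio of 1.24 (0.863 to 1.78). Superficial-epidermis-like cells, the outermost skin layer, made up 2.06% of the LPS library and 5.73% of the control library, a ratio of 0.360 (0.317 to 0.408). The fast-muscle-like share was 2.90-fold (2.46 to 3.43) higher in the LPS library, but this rests on cluster 18, at 6.29-fold, whose LPS cells had a median of 795 UMIs, while cluster 49 gave 0.880 (0.667 to 1.16); at resolution 1 the class ratio was 0.962. Hepatocyte-like and ionocyte-like shares were each 2.18-fold higher, the former 1.28-fold at resolution 1, and the fibroblast-like share was 1.82-fold (1.71 to 1.95) higher, at 14.3% against 7.83%. Enterocyte-like and mucous-goblet-like cells had ratios of 0.771 (0.668 to 0.889), which turned to 1.8 with the stricter cell filter, and 0.774 (0.603 to 0.990). Basal-epidermis-like cells, at 390 and 490, gave 0.986 (0.861 to 1.13). The other 9 of the 19 classes with at least 50 cells in both libraries had ratios between 0.995 (radial-glia-like) and 1.77 (exocrine-pancreas-like).

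The protocol names tail regions and the tissue label reads body, yet both libraries held hepatocyte-like (348 LPS and 198 control), exocrine-pancreas-like (375 and 262) and enterocyte-like (318 and 511) cells. Both also held unnamed cluster 52, with the heart genes myl7, cmlc1 and nppa among its leading genes (100 LPS and 143 control cells). The same holds for unnamed cluster 33, with the inner-ear genes stm, otomp and otog (177 and 175). By these markers, tissue from outside the tail was not limited to the LPS library. What tissue went into each pool is not settled by the labels, and any difference in dissection is part of each share ratio. Unnamed cells made up 49.4% of the LPS library and 60.5% of the control library, which sets part of every share. Most of them lay in 4 low-depth clusters, 1 mostly of the LPS library (4191 of its cells, median 772 UMIs) and 3 mostly of the control library (7975 cells, median 1153). With the stricter cell filter the superficial-epidermis-like ratio was 0.641, the mucous-goblet-like class was not named and the other classes lay between 1.04 (fast-muscle-like) and 3 (ionocyte-like). The macrophage-like ratio was 0.738 with only cells in named classes as the denominator, 1.61 with this filter and 0.613 with response genes kept among the clustering genes. Unnamed clusters outside the low-depth ones held 21.0% and 18.9% of cells. Among these, cluster 45, led by agr2, cxcl8a, muc5.3 and krt15, held 198 LPS cells and 1 control cell, and cluster 47, led by mmp13a, fabp1b.1 and mmp9, held 111 and 0. Neither was counted in a class. Named by their best-scoring markers, along with other such clusters, they brought the mucous-goblet-like ratio to 2.18 and the enterocyte-like ratio to 0.988.

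**Figure D1:**
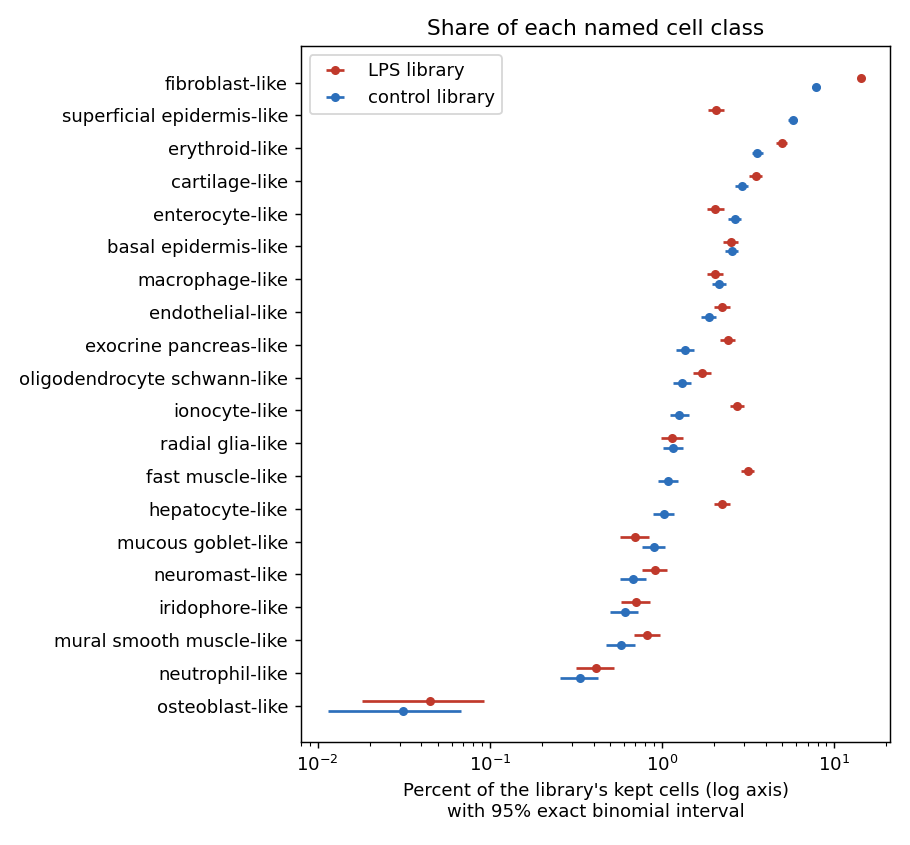
Percent of each library's kept cells in each named class (x axis, logarithmic), LPS library in red and control library in blue, bars giving exact binomial 95% intervals. The superficial-epidermis-like points lie apart at 2.06% and 5.73%, while the macrophage-like points lie at 2.03% and 2.15%.

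The leucocyte chemoattractant cxcl18b was 1.38-fold (1.29 to 1.48) higher and il1b 1.29-fold (1.17 to 1.41) higher on the standardised scale, but with every class weighted equally the il1b log2 ratio was -0.72. The neutrophil chemoattractant cxcl8a had a ratio of 0.972 (0.902 to 1.05). These levels cover named classes only. Cluster 45, with cxcl8a among its leading genes and 198 LPS cells against 1 control cell, was unnamed and lies outside this value. Tumour necrosis factor genes were lower on this scale: tnfb by 1.32-fold (1.16 to 1.5), though it was higher in 3 of 7 classes with at least 30 UMIs. With 3 UMIs against 30, tnfa was 6.72-fold (2.09 to 34.5) lower, a log2 ratio of -2.75 that was -0.81 with every class weighted equally. The suppressor of cytokine signalling socs3a was 2.21-fold (2.16 to 2.27) lower, at 260 against 576 CPM, and lower in 19 of 19 classes; with an estimated background subtracted, the oligodendrocyte/Schwann-like value turned to 0.23 (log2). Its paralogue socs3b was 1.47-fold lower. The NF-kB inhibitor genes nfkbiaa and nfkbiab, which are themselves NF-kB targets, had ratios of 0.916 (0.885 to 0.949) and 1.00 (0.964 to 1.04). The enzyme acod1, made by activated macrophages, was 2.66-fold (1.68 to 4.40) lower and csf3a 2.1-fold (1.3 to 3.52) lower. On the log2 scale acod1 was at -0.80 without the 5 highest cells, and csf3a ranged from -2.33 with every class weighted equally to -0.50 without standardisation. The genes csf3b, at 1.18 (0.855 to 1.61), and saa, at 0.866 (0.690 to 1.08), had intervals that include 1. The LPS receptor-family genes tlr4ba and tlr4bb gave 1.91 (1.38 to 2.65) and 1.65 (0.660 to 4.19), with tlr4ba at -0.03 (log2) in thinned cells, and the adaptor myd88 gave 1.03 (0.910 to 1.16). Lower still by less than 1.5-fold were tnfaip2b, by 1.26-fold, and the macrophage gene mpeg1.1, by 1.34-fold. In thinned cells tnfaip2b turned to 0.09 and nfkbiaa to 0.19 (log2). Only 16 UMIs of il6 and 17 of il11b were counted in the named classes, and none of il10, so no statement on these 3 is possible at this depth; the il11b ratio of 3.92 (1.22 to 14.9) turned to -0.26 (log2) with clusters as strata.

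The lists fixed before the data were examined moved in different directions. Their values cover named classes only, and so leave out clusters 45 (198 LPS cells and 1 control cell) and 47 (111 and 0). Of 36 measured inflammatory cytokine and chemokine genes, 5 were at least 1.5-fold higher and 11 at least 1.5-fold lower in the LPS library, and their median log2 ratio was -0.20 (range of count redraws -0.33 to -0.09), at percentile 0.09 of 10000 random lists matched on level. The chemokine ccl35.1 was 3.53-fold (3.05 to 4.1) lower, ccl20a.3 2.70-fold (2.31 to 3.18) lower and ccl19a.2, with 3 against 77 UMIs, 21.3-fold (7.02 to 106) lower, while cxcl8b.1 was 2.58-fold (2.19 to 3.05) higher. With cells thinned to a common depth this median was 0.088. Of 31 NF-kB pathway and feedback genes, 6 were higher and 1 lower, with a median of 0.15 (0.08 to 0.29) at percentile 83.1; nfkb1 was 2.06-fold (1.56 to 2.71) higher, cflara 1.93-fold (1.76 to 2.11) higher and tnfaip3 1.70-fold (1.44 to 2.02) lower. The LPS and Toll-like receptor sensing list had 6 of 33 genes higher and 3 lower, with a median of 0.04 at percentile 27.9. Its inflammasome adaptor pycard was 3.88-fold (3.57 to 4.22) lower, and tlr18 and tlr22 were 2.29-fold and 1.86-fold higher.

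Most lists of other immune functions had medians below 0, with most members not past the 1.5-fold rule. Antigen presentation had 0 of 27 genes higher and 5 lower, a median of -0.43 below all 10000 random lists, with mhc2a 2.22-fold (1.79 to 2.78), b2m 1.95-fold (1.58 to 2.43) and cd74a 1.45-fold (1.31 to 1.61) lower. Complement had 1 of 30 higher and 4 lower, a median of -0.33 at percentile 0.01; c3a.1 was 1.55-fold lower and c7b 3.51-fold (3.22 to 3.84) higher, and without standardisation this median was 0.03. Acute-phase and antibacterial genes had 5 of 35 higher and 9 lower (median -0.21, percentile 0.055). Among them 1 identifier of haptoglobin (hp) was 13.1-fold (8.23 to 22.2) lower, from 19 against 251 UMIs, and this value leaves out any other identifier of that symbol. The prostaglandin synthase ptgs2b was 3.44-fold (3.14 to 3.76) higher and the iron hormone hamp 1.79-fold (1.73 to 1.86) higher. Interferon-stimulated genes had 3 of 35 higher and 8 lower (median -0.13, percentile 1.21); isg15 was 2.78-fold (2.17 to 3.60) and mxc 2.95-fold (2.14 to 4.16) lower, and ifit11 was 2.2-fold higher. Phagocyte markers had 1 of 24 higher and 2 lower (median -0.22, percentile 0.06), with the granule enzyme gene mpx 2.03-fold (1.76 to 2.35) lower, at -0.38 (log2) with clusters as strata. In the JAK-STAT and SOCS list, 3 of 31 were higher and 2 lower (median 0.24, percentile 97.55), with jak1 1.53-fold higher and cish 1.70-fold lower.

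The lists of tissue remodelling, glucocorticoid response, the clock, hypoxia and lipid oxidation had medians above 0. Of 37 matrix remodelling and wound genes, 9 were higher and 3 lower (median 0.32, percentile 99.7), led by the growth factor areg at 6.32-fold (5.42 to 7.40); plaua was 3.19-fold (2.45 to 4.21) lower. The file held 2 genes named mmp13a, a collagenase, at 1.36-fold (1.19 to 1.57) and 3.41-fold (3.09 to 3.76) higher, with log2 ratios over all settings of 0.15 to 1.21 and 0.96 to 2.57. Glucocorticoid-response genes had 11 of 31 higher and 1 lower (median 0.29, percentile 99.9), with g0s2 at 2.99-fold and pfkfb4b at 2.5-fold. The clock list had 11 of 38 higher and 0 lower (median 0.42, above all random lists), with per1a 2.15-fold (1.90 to 2.43) higher and dbpa 2.14-fold higher. Hypoxia genes had 12 of 36 higher and 0 lower (median 0.35, percentile 99.9), with ndrg1b at 17.4-fold (8.68 to 39.8) from 98 against 9 UMIs and admb at 3.05-fold. Lipid oxidation and fasting genes had 12 of 33 higher and 0 lower (median 0.35), with cpt1b, which carries fatty acids into mitochondria, 2.67-fold (2.46 to 2.89) higher and ucp2 2.15-fold higher. Sterol and lipid synthesis had 6 of 38 higher and 1 lower (median 0.25, percentile 99.3), with hmgcs1 2.51-fold higher; extracellular matrix had 9 of 74 higher and 0 lower (median 0.18, percentile 99.4), with elnb 4.58-fold higher. Heat-shock genes had 6 of 33 higher and 1 lower (median 0.19, percentile 95.6), with the chaperone gene dnajb1b 1.77-fold higher. The unfolded-protein-response list had 6 of 36 higher and 0 lower (median 0.17, percentile 94.6), with trib3 1.82-fold higher, but its median was -0.05 in thinned cells. Xenobiotic-response genes had 6 of 24 higher and 0 lower (median 0.23, percentile 97.6), with cyp2k18 4.25-fold higher; without the 5 cells richest in each gene the median was -0.02.

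Cell-cycle and sarcomere lists had medians below 0, with most members within 1.5-fold. The cell-cycle list had 1 of 55 genes higher and 8 lower (median -0.38, below all random lists), with ccnb1 1.89-fold (1.58 to 2.26) and mcm7 1.79-fold lower. This median covers named classes only. Cluster 5, with the cell-cycle genes mki67 and top2a among its leading genes, was unnamed and lies outside it. That cluster held 200 LPS and 250 control cells, a share ratio of 0.992 (0.819 to 1.199). The median therefore does not show fewer dividing cells in the LPS library. Immediate-early genes, induced within minutes of many stimuli including dissociation, had 2 of 44 higher and 12 lower (median -0.23, percentile 0.01), with nr4a1 2.35-fold and egr2b 2.24-fold lower and klf11b 2.46-fold higher. Sarcomere genes had 4 of 55 higher and 19 lower (median -0.34), with pvalb3 9.13-fold (6.85 to 12.4) and pvalb1 2.34-fold lower, though the median was 0.07 after background subtraction. Nuclear genes of oxidative phosphorylation had 0 of 79 higher and 2 lower, with a median of -0.13 at percentile 0.20. Medians of glycolysis (0.05, 4 of 32 higher and 1 lower), oxidative-stress genes (0.02, 5 of 38 and 0), p53 and apoptosis genes (0.0852, 6 of 27 and 0) and keratin and barrier genes (-0.00, 9 of 60 and 9) lay between percentiles 38 and 67.4. The lactate carrier gene slc16a3, on the glycolysis list, was 6.87-fold (5.85 to 8.09) higher, and the tight-junction gene cldne, on the barrier list, was 2.82-fold (2.77 to 2.88) higher.

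**Figure D2:**
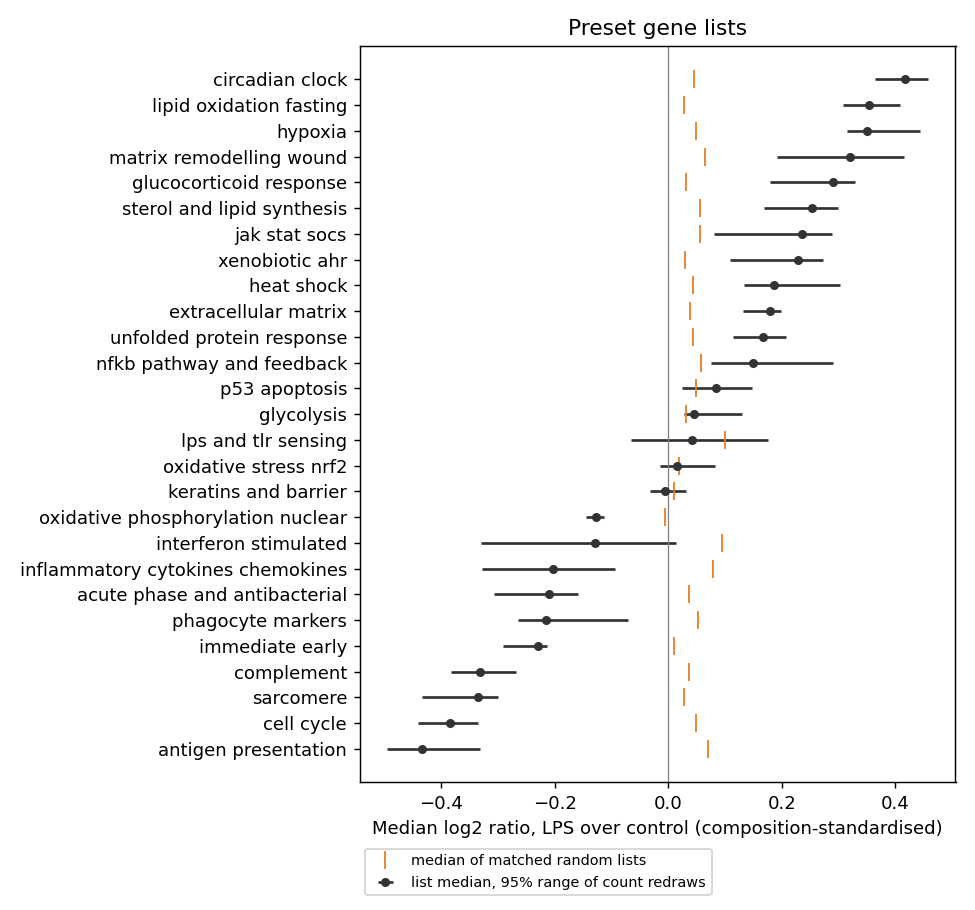
Median log2 ratio of the LPS library over the control library for each preset gene list (x axis), with the 95% range over redraws of the counts and, as a vertical tick, the median of random lists matched on level. The circadian clock list lies highest at 0.42 and antigen presentation lowest at -0.43.

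In the skin, as in the other classes with enough UMIs, mmp9 was higher in the LPS library in both epidermal classes and in ionocyte-like cells, the ion-transporting cells of larval skin, and il1b in both epidermal classes. In basal-epidermis-like cells mmp9 (ENSDARG00000042816) stood at 386 against 50.9 CPM, 7.58-fold (6.67 to 8.63) higher, and il1b (ENSDARG00000098700) at 42.0 against 2.94, 14.3-fold (8.61 to 25.2) higher. This class was held mostly by cluster 16 in the LPS library (250 cells, against 140 in cluster 43) and by cluster 43 in the control library (258 cells, against 232 in cluster 16). Cluster 43 held 137 of the 141 LPS and 6 of the 17 control UMIs of il1b in this class, too few in cluster 16 for a ratio there. Inside cluster 43 alone the il1b fold was 40.8 (18.3 to 113) and the mmp9 fold 7.84 (6.89 to 8.96), and inside cluster 16 the mmp9 fold was 7.61 (4.03 to 15.6). In ionocyte-like cells mmp9 was 32.5-fold (18.4 to 63.4) higher, at 136 against 4.17 CPM, il1b 8.67-fold (3.95 to 22.5) higher and the second mmp13a gene 25.1-fold (13.4 to 53) higher. On the log2 scale this mmp9 value was 5.02, and 1.85 in thinned cells, where basal-epidermis-like mmp9 was at 2.30 and ionocyte-like il1b turned to -0.42, and the mmp13a value was 0.68 with the stricter cell filter. In superficial-epidermis-like cells il1b was 20.6-fold (12.06 to 36.9) higher, a log2 ratio of 4.36 that fell to 2.75 without the 5 highest cells, and mmp9 4.14-fold (2.54 to 6.69) higher. These UMIs were unevenly spread over cells. In the LPS library 5 cells held 59.6% of the il1b UMIs of basal-epidermis-like cells and 80.0% of those of superficial-epidermis-like cells. In ionocyte-like cells 5 cells held 63.1% of the mmp9 UMIs. For cxcl8a the basal-epidermis-like ratio was 0.942 (0.846 to 1.05), and cxcl18b was 2.46-fold (1.83 to 3.35) lower in that class but 1.69-fold (1.55 to 1.84) higher in fibroblast-like cells.

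Counted by cell at a common depth of 700 UMIs, mmp9 was found in 11.3% of LPS and 2.93% of control basal-epidermis-like cells (26.9% and 13.1% unthinned, at median depths of 5132 and 5960 UMIs). The corresponding shares in ionocyte-like cells were 6.28% and 2.16% (12.18% and 3.29% unthinned, medians of 3329 and 7477). Erythroid-like cells, which should lack the gene, had 1.76% and 0.289% (3.37% and 0.434% unthinned, medians of 1215 and 1702), and superficial-epidermis-like cells had 1.88% and 0.184% (4.98% and 1.90% unthinned, medians of 4286 and 6327). A UMI of il1b was found in 1.58% of LPS basal-epidermis-like cells and in 0 of 478 control cells (6.67% and 2.65% unthinned). With 3 counts taken as the limit of a count of 0, this allows up to 0.628% of cells with a UMI at this depth. That limit is not the exact interval used for other shares, and it sets no limit on cells expressing the gene. In superficial-epidermis-like cells the il1b shares were 1.88% and 0.0918% (4.98% and 1.45% unthinned), against 0.441% and 0.289% of erythroid-like cells (0.518% and 0.868% unthinned).

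**Figure D3:**
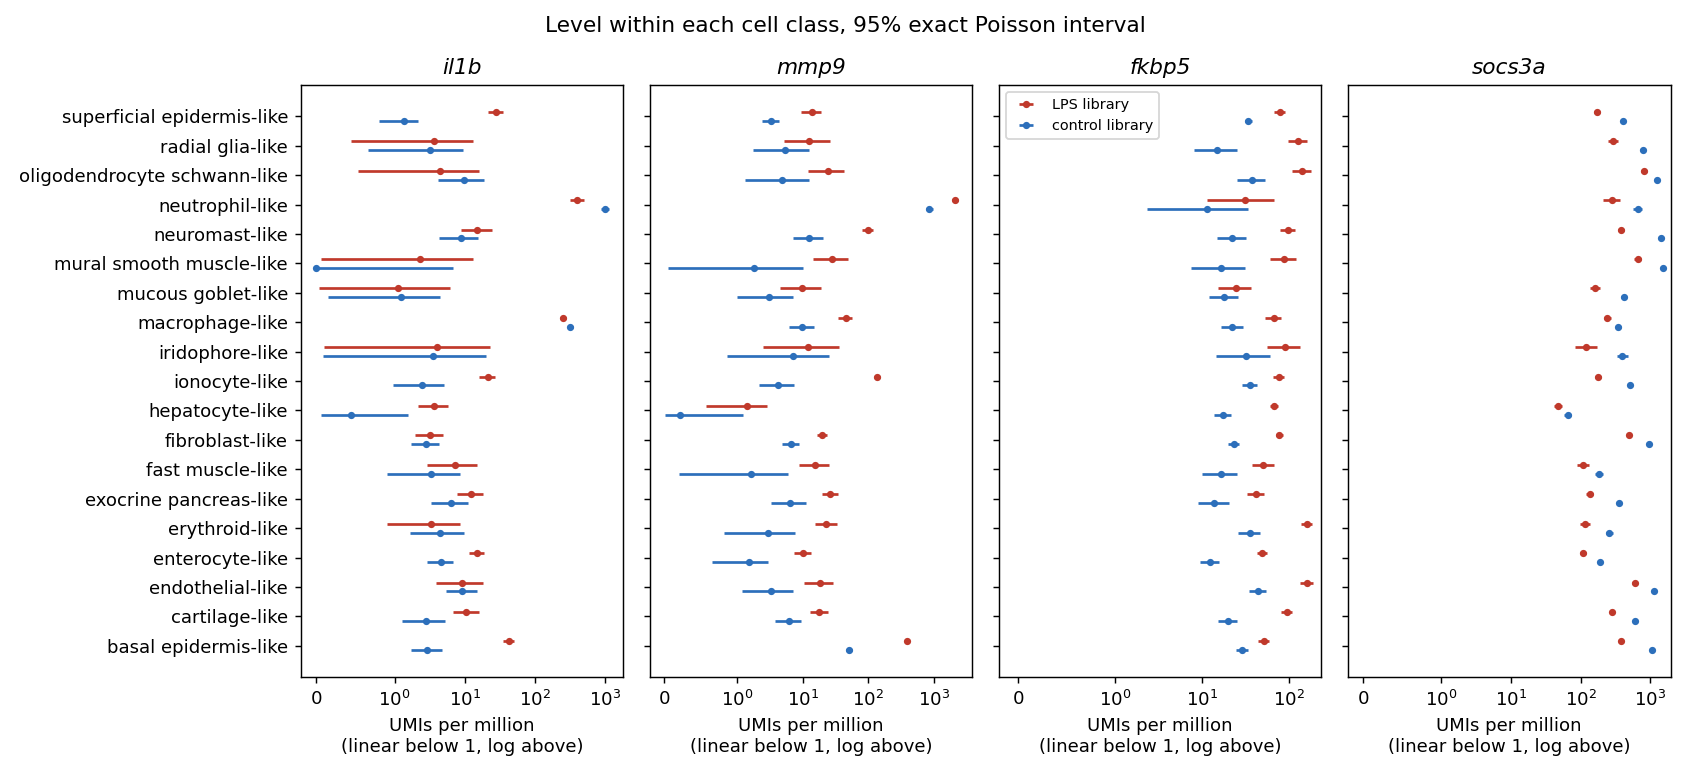
Levels of il1b, mmp9, fkbp5 and socs3a in each class (x axes, CPM, linear below 1 and logarithmic above), LPS library in red and control library in blue, bars giving exact Poisson 95% intervals. In basal-epidermis-like cells mmp9 lies at 386 and 50.9, and in neutrophil-like cells il1b lies at 400 and 987.

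In the phagocytes several inflammatory genes were lower in the LPS library. Neutrophil-like cells had il1b at 400 against 987 CPM, 2.47-fold (1.91 to 3.23) lower, and mpx 2.34-fold (1.98 to 2.78) lower, a log2 ratio of -1.23 that was -0.36 in thinned cells, while mmp9 was 2.46-fold (2.08 to 2.90) higher and lysozyme (lyz) 6.65-fold (6.21 to 7.13) higher. The estimated background in these cells was 57.7% of LPS and 33.1% of control UMIs. Macrophage-like cells had il1b 1.27-fold (1.12 to 1.45) lower, cxcl8a 2.05-fold (1.70 to 2.48) lower, tnfb 1.42-fold (1.21 to 1.66) lower and acod1 2.49-fold (1.55 to 4.18) lower, and mmp9 was 4.61-fold (2.80 to 7.87) higher. The il1b values turned to 0.42 (macrophage-like) and 0.17 (neutrophil-like) on the log2 scale in thinned cells, and tnfb in macrophage-like cells to 0.07, opposite in sign to the values from all counts. In thinned cells il1b was found in 14.2% and 9.16% of macrophage-like cells (43.4% and 30.6% unthinned, medians of 3201 and 2681) and in 26.3% and 21.9% of neutrophil-like cells (40.6% and 53.1% unthinned, medians of 1758 and 2101). The inflammatory list in macrophage-like cells had 6 of 22 genes higher and 8 lower, a median of -0.48 at percentile 0.11, and complement had 0 of 20 higher and 12 lower, a median of -0.87. Lyz in macrophage-like cells was 31.7-fold higher, but 5 cells held 98.5% of its UMIs, and without them the log2 ratio was -0.89. By the rule of size, the chemokines cxcl11.5 (1 against 139 UMIs, 87.6-fold lower, 15.5 to 3486) and cxcl11.6 (12.0-fold lower, 7.17 to 21.8) and the interferon-stimulated isg15 (9.95-fold lower, 6.26 to 16.8) were among the lowest genes of macrophage-like cells; they were counted in 16, 22 and 26 control cells, 5 of which held 77.0%, 84.3% and 54% of the UMIs. In thinned cells cxcl11.6 was at -1.42, isg15 at -2.47, acod1 at -0.58 and mmp9 at 1.42 (log2). In neutrophil-like cells abcc13 (15.8-fold, 6.92 to 44.6) and cfd (9.50-fold, 5.77 to 16.5) were among the highest, though 5 cells held 94.4% of the LPS cfd UMIs and without them the cfd log2 ratio was 0.25. Among the lowest were krt94 (42.4-fold, 11.5 to 354) and fgfbp2b (18.4-fold, 6.07 to 91.3). For krt94, 5 cells held 94.8% of the control UMIs, and its log2 ratio in thinned cells was -2.29. For fgfbp2b, 5 of 17 control cells held 68%, and the low-depth clusters held 71.9 (LPS) and 126 (control) CPM. The first is on the preset basal-epidermis list and the second led cartilage-like cluster 31, so RNA of other cells may underlie both, which was not tested.

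The dioxin-inducible enzyme cyp1a was 11.3-fold (9.27 to 13.8) higher in superficial-epidermis-like cells, 7.12-fold (4.05 to 13.5) higher in ionocyte-like cells and 3.08-fold (2.55 to 3.73) higher in endothelial-like cells, but 1.95-fold (1.75 to 2.18) lower in hepatocyte-like cells. In thinned cells the superficial-epidermis-like log2 ratio of cyp1a fell from 3.50 to 2.18 and the ionocyte-like one from 2.83 to 0.75. In hepatocyte-like cells hamp stood at 1516 against 761 CPM, 1.99-fold (1.91 to 2.07) higher. The glucocorticoid-receptor co-chaperone fkbp5 (ENSDARG00000028396) was higher in 18 of 18 classes with at least 30 UMIs, from 1.35-fold (0.740 to 2.44) in mucous-goblet-like to 8.36-fold (4.66 to 16.1) in radial-glia-like cells, and per1a was higher in 14 of 14; with looser names 1 class had per1a lower. In thinned cells only 7 classes reached 30 UMIs of fkbp5 and 1 of per1a, each higher. Below that floor mucous-goblet-like fkbp5 turned to -0.17 (log2), and per1a to -0.89 in endothelial-like and -0.56 in superficial-epidermis-like cells. For socs3a (ENSDARG00000025428) the class values ranged from 3.78-fold lower in neuromast-like to 1.37-fold lower in hepatocyte-like cells. In fast-muscle-like cells, held mostly by cluster 18 in the LPS library (396 cells, against 93 in cluster 49) and by cluster 49 in the control library (131 cells, against 78), fkbp5 was 3.06-fold (1.78 to 5.43) higher. Superficial-epidermis-like cells had the most genes past 2-fold, 1322 higher and 962 lower of 11176 at the floor. Among them arf4b was 34.7-fold (29.1 to 41.7) higher and slc16a3 30.0-fold (21.4 to 43.0) higher, while the interferon-inducible GTPase gene irge1 had 0 against 525 UMIs and rasd1 was 18.2-fold (7.76 to 56.3) lower, at -1.82 (log2) in thinned cells. Fibroblast-like cells had 707 genes higher and 429 lower of 13011, basal-epidermis-like cells 341 and 554 of 10199, and macrophage-like cells 230 and 454 of 7438. Neutrophil-like cells had 133 and 269 of 1425, a larger share of the genes at the floor than in superficial-epidermis-like cells.

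**Figure D4:**
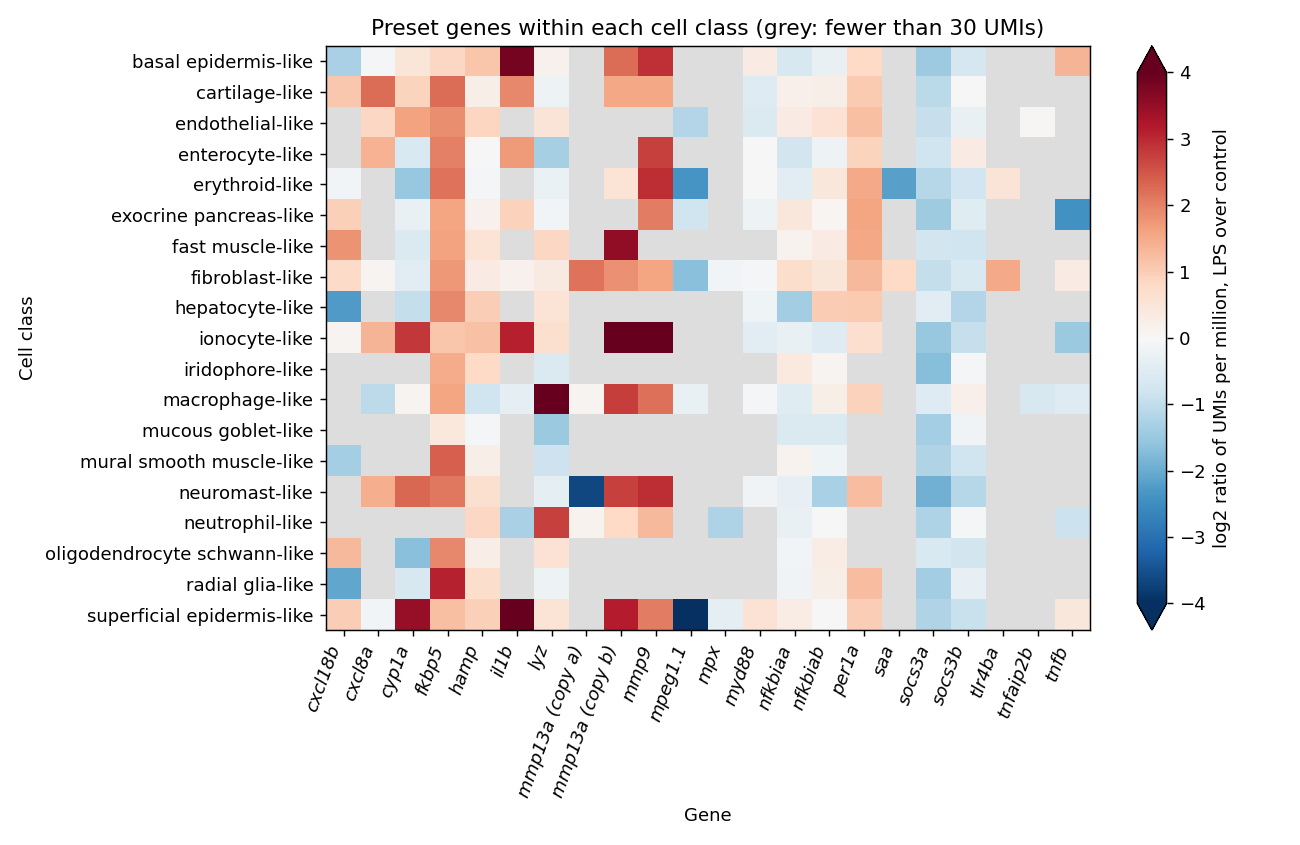
Log2 ratio of CPM, LPS over control, for preset genes (x axis) in each class (y axis), with red for higher and blue for lower in the LPS library, grey for fewer than 30 UMIs, colours ending at 4 and -4, and a count of 0 in 1 library drawn at the end of the scale. The fkbp5 column is red in 18 classes and the socs3a column blue in 19.

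Over all 13621 genes with at least 200 UMIs, 367 were at least 2-fold higher and 234 at least 2-fold lower in the LPS library on the standardised scale, counts by size and interval, not test calls. The median log2 ratio was 0.05, with 5th and 95th percentiles of -0.63 and 0.81. Scaling by TMM factors gave 286 and 318, which turns the balance between the directions. The highest genes were mostly of vision: rod opsin (rho) at 392.2-fold (153 to 1442), the cone genes opn1sw1, opn1mw1, opn1lw2, arr3a (170-fold), gngt2b and pde6ha (49.8-fold), and the retinal genes crx, vsx1 and rs1a, together with the calcium-binding gene pvalb5 at 277-fold and arf4b at 27.5-fold (23.2 to 32.6). In the low-depth clusters 21 photoreceptor genes summed to 1301 CPM in the LPS library and 7.61 in the control library. The lowest genes included irge1 (0 against 595 UMIs), si:dkey-22i16.7 at 30.6-fold (28.4 to 33), CR385050.2 at 21.1-fold, the pancreatic elastase genes cela1.5 at 25.4-fold (13.5 to 53.7) and cela1.3 at 14.0-fold, hp, and cyp21a2 at 13.5-fold (7.51 to 26.6). With clusters as strata cela1.3 was at -1.62 (log2), and after background subtraction rho was at 5.51, arr3a at 3.72 and pde6ha at 2.42. Over all settings log2 ratios ran from -6.36 to -3.43 for cela1.5 and from -4.20 to -2.82 for hp. Those of cyp21a2 ran from -4.21 to -2.73, and those of arf4b from 3.44 to 5.83. In basal-epidermis-like cells at most 5 cells per library held all UMIs of CR385050.2, and 5 cells per library at least 99.95% of those of si:dkey-22i16.7, and in thinned cells their standardised log2 ratios were -0.17 and -1.78. The LPS low-depth clusters held 4.12 CPM of cela1.5 and the control ones 18.9. Without genes whose level was no higher than in the low-depth clusters, 183 genes were higher and 133 lower.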

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

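The tests of mmp9, of fkbp5 and of free photoreceptor RNA were chosen after the result was seen, and the lens-gene test was set before its result was seen.

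Signals outside the named classes drew attention because the control library held almost no such cells. Cluster 30, with rho, gngt2b, arr3a and crx, had 251 LPS cells and 0 control cells. Cluster 48, with the pigment-epithelium genes rpe65a and rgra and the pigment genes tyrp1b and dct, had 26 and 0. Cluster 45, with agr2, cxcl8a, muc5.3, krt15 and irg1l, had 198 LPS cells and 1 control cell, and cluster 47, a mixed cluster with mmp13a, fabp1b.1 and mmp9, had 111 and 0. The rule flagged only clusters mostly of the LPS library. Smaller clusters of the control library also existed outside the low-depth ones. Cluster 53, led by fabp6 and slc15a2, had 0 LPS and 27 control cells, cluster 21 had 0 and 15, and cluster 41 had 0 and 13.

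Other values drew attention because a gene was higher in 1 class of the LPS library and lower in another. The log2 ratio of il1b was 5.14 greater in basal-epidermis-like than in neutrophil-like cells, and that of cyp1a 4.46 greater in superficial-epidermis-like than in hepatocyte-like cells. For cxcl8a the gap between ionocyte-like and macrophage-like cells was 2.39, for cxcl18b between fibroblast-like and basal-epidermis-like cells 2.05, and for nfkbiab between hepatocyte-like and neuromast-like cells 2.29. The gap of 6.30 for lyz between macrophage-like and enterocyte-like cells rests on 5 macrophage-like cells, without which the macrophage-like value was -0.89. In thinned cells neutrophil-like il1b turned to 0.17 and ionocyte-like cxcl8a to -0.51, so for these 2 genes the opposite directions did not hold there. With 1 library per group none of these differences was tested.

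Higher mmp9 in basal-epidermis-like and ionocyte-like cells of the LPS library was set against neutrophil RNA and an estimated free-RNA background. Had the mmp9 come with neutrophil RNA, free or in doublets, the granule genes lyz, npsn and mpx would have come along. Across the epidermal and ionocyte-like classes they reached at most 18.5% of the level needed. Doublets with other cells that carry mmp9 were not tested, and no doublets had been removed. An estimated free-RNA background accounted for at most 7.495% of mmp9 in basal-epidermis-like and ionocyte-like cells, which argues against it as the source there. In superficial-epidermis-like cells it accounted for 53.6% (interval 38 to 78.4, counting error of the class mmp9 level only), which leaves that class open. The background share of this class, 14.8% by haemoglobin RNA, was taken as known. Photoreceptor RNA gave a share of 7.82%, which would lower the 53.6%. The free-RNA test was split by class after the 53.6% was seen. A difference between pools or lanes other than LPS cannot be told apart from LPS with 1 library per group, so a response of these cells to LPS is untested.

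Higher fkbp5, in 18 of 18 classes from all counts, kept a standardised log2 ratio of 1.59 after background subtraction and of 1.86 in cells thinned to 1 depth. Of classes with at least 30 UMIs, 15 and 7 had it higher under these settings and 0 lower. The low-depth clusters held 69.4 against 20.5 CPM of fkbp5, close to the standardised 74.3 against 24.3. Subtracting a background with a similar ratio could change the ratio little, so this value cannot decide on free RNA. It shows only that a background of the estimated size was not the whole source. Levels were already scaled to a common total, so thinning bears little on depth. Handling stress, time of day at collection or LPS could each raise a glucocorticoid-responsive gene in every class, and with 1 library per group they cannot be told apart.

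Photoreceptor RNA in the classes of the LPS library is consistent with free RNA. In 14 of 18 non-erythroid classes its level, relative to the low-depth clusters, lay within 2-fold of that of haemoglobin RNA, with quotients of 0.346 to 0.917, all below 1. A candidate source is eye tissue in the LPS pool. Cluster 30, with photoreceptor genes, held 251 LPS cells and 0 control cells. Cluster 48, with pigment-epithelium genes, held 26 and 0, so the 2 libraries differed in these cells. Lens genes, a list of 26 set before the test, stood at 213 CPM in the LPS low-depth clusters and 4.19 in the control ones, a ratio of 50.9 (37.5 to 70.6). The protocol describes tail regions, and the test does not show how eye RNA reached the pool.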

How the results depend on the processing

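The alternatives with the 5 highest cells of each gene left out, looser names, naming of clusters of 1 library, named classes as denominator, every alternative for shares other than macrophage-like and neutrophil-like, the highest doublet scores removed and low-depth genes left out were chosen after the result was seen.

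Across all alternatives that gave a value, standardised mmp9 ranged from 1.60 to 2.84 on the log2 scale, fkbp5 from 1.49 to 1.86, per1a from 0.93 to 1.43, lyz from 1.09 to 3.46, hamp from 0.45 to 1.15 and socs3a from -1.23 to -1.02. In basal-epidermis-like cells mmp9 ranged from 2.30 to 3.32 and il1b from 3.62 to 4.53, with no thinned il1b value since the control count was 0. A value stayed when inside the counting interval of its first value (for lists, the range of redraws), and moved when outside it. It reversed when that interval excluded 0 (1 for shares) and the sign changed, so sign changes of values near 0 are not listed. Among these, medians fell to -0.036 for the LPS sensing list and -0.111 for oxidative stress, ran from -0.217 to 0.117 for keratins, and standardised saa and cxcl8a reached 0.35 and 0.48. Counts of genes moved when changed over 1.5-fold. Of all values under alternatives, 340 class-gene values moved, 49 reversed and 3331 stayed; for list medians these were 104, 6 and 290, for standardised genes 173, 7 and 580, and for other class shares 36, 7 and 122. Keeping called doublets changed nothing, as none were called. This setting and the other floors each left all 305 class-gene values the same, which enlarges the stayed count. In thinned cells 111 class-gene values moved, 24 reversed and 147 stayed. For the values below the cause was not tested, except that fewer genes pass where counts are thinned, the floor is raised or genes are left out.

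The macrophage-like share ratio was 1.61 with the stricter filter, 0.613 with response genes kept in clustering and 0.738 with named classes as denominator. Counts of genes higher and lower were 594 and 365 without standardisation, 116 and 103 in thinned cells, 215 and 148 with other floors, and 183 and 133 with low-depth genes left out. With the 5 highest cells out 311 genes were higher and 383 lower. The inflammatory list median was 0.088 in thinned cells and -0.075 with the 5 highest cells out. The NF-kB median was 0.014 with equal weights, 0.061 with TMM and 0.073 with the 5 highest cells out.

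Other shares reversed: fast-muscle-like to 0.962 at resolution 1 and 0.989 with every barcode, enterocyte-like to 1.01 and, with the stricter filter, 1.8, mucous-goblet-like to 2.18 with clusters of 1 library named, and cartilage-like to 0.945 and endothelial-like to 0.932 with named classes as denominator. The hepatocyte-like ratio ranged from 1.28 to 2.25. Mucous-goblet-like cells were not named in the other clusterings, nor basal-epidermis-like cells at resolution 1, so these gave no value.

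Other list medians whose range excluded 0 reversed: complement to 0.027 without standardisation, unfolded protein response to -0.049 in thinned cells, glycolysis to -0.032 and p53 to -0.021 with TMM, xenobiotic response to -0.018 with the 5 highest cells out, and sarcomere to 0.068 with background subtracted.

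In thinned cells the reversed log2 ratios were, on the standardised scale, 0.19 for nfkbiaa, 0.088 for tnfaip2b, -0.032 for tlr4ba and 0.060 for CR385050.3. In basal-epidermis-like cells they were 0.12 for CR385050.2, 0.24 for CR385050.3, 0.0091 for nfkbiab and 0.33 for socs3b, and in enterocyte-like cells -0.31 for zgc:165423, 0.030 for nfkbiaa, 0.33 for nfkbiab and -0.31 for cxcl8a. Macrophage-like cells had 0.42 for il1b, 0.44 for nfkbiaa and 0.07 for tnfb, and neutrophil-like cells 0.17 for il1b. The rest were -0.86 for saa in fibroblast-like, -0.51 for cxcl8a and -0.42 for il1b in ionocyte-like, -0.54 for mmp9, -1.13 for cxcl8a, -1.13 for cyp1a and -0.129 for the second mmp13a gene in neuromast-like, -0.887 for per1a in endothelial-like, 0.027 for lyz in mucous-goblet-like and -0.038 for lyz in oligodendrocyte/Schwann-like cells, and -0.56 for per1a and 0.089 for socs3b in superficial-epidermis-like cells.

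With the 5 highest cells out, standardised cyp1a was -0.018, cyp1a in cartilage-like cells -0.61, cxcl8a there -0.814, hce2l2 in basal-epidermis-like cells 0.78, lyz in macrophage-like cells -0.89, s100a11 in enterocyte-like cells -1.58 and saa in fibroblast-like cells -1.42. With every barcode, hamp in fast-muscle-like cells was -1.06, saa in fibroblast-like cells -3.44, cyp1a in fibroblast-like cells 0.60, s100a11 in enterocyte-like cells -1.39, lyz in macrophage-like cells -0.89 cxcl18b in mural-smooth-muscle-like cells 1.09 and socs3b in exocrine-pancreas-like cells 0.027. At resolution 1, hamp in fast-muscle-like cells was -1.06, lyz there -0.069, nfkbiaa in exocrine-pancreas-like cells -0.22, cxcl18b in mural-smooth-muscle-like cells 1.108 and the saa in fibroblast log2 ratio -2.37. The stricter filter gave -1.30 for hamp in fast-muscle-like and 0.24 for cyp1a in enterocyte-like cells, and response genes kept in clustering gave -1.13 for hamp and -0.073 for cxcl18b in fast-muscle-like cells. Standardised il1b was -0.72 with equal weights and il11b -0.26 with clusters as strata. Background subtraction gave 0.23 for socs3a in oligodendrocyte/Schwann-like cells, and looser names gave -0.013 for nfkbiaa in superficial-epidermis-like and 0.981 for cxcl18b in mural-smooth-muscle-like cells.

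The genes tnfa, il6, il11b and tlr4bb had at most 33 UMIs over both libraries, which limits what their ratios show.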
